A study of Myzus persicae with 16 samples.

How the data were processed

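Each of the 16 arrays was a spot-level scanner file of an Agilent aphid array with 15744 spots, 1116 of them controls. Intensity values are median pixel signals of the spot and its local background in the green and red channels, extracted with Feature Extraction 10.5.1.1 per the file headers. Processed intensities, background-subtracted and dye-normalised, and their log10 ratio of red over green also came from Feature Extraction per the file headers. The authors deposited a matrix of log2 ratios, 1 column per array, and a table of mean log2 ratios with a p-value for each of the 4 comparisons; the deposited p-value columns were used only as an alternative. The submitters' processing notes name limma and no version. How those ratios were normalised is not given in the sources used here. Set against the scanner's ratios, the deposited log2 matrix columns correlated at 0.912 to 0.959 in size, with slopes of 0.688 to 0.849 on the log2 scale and medians between -0.0165 and 0.00999. They ran channel 1 over channel 2 in 3 of the comparisons and channel 2 over channel 1 in the rearing comparison of exposed aphids, so for that comparison the header of the authors' deposited table runs against the dyes of the labels. The headers of the authors' deposited table give Col-0 over 35S:EBFS for both rearing comparisons, and these columns were first turned to 35S:EBFS over Col-0. The mean ratios so turned correlated with those computed here at 0.9996 for the EBF response of Col-0 reared aphids, -0.9994 for the rearing comparison of exposed aphids, 0.9991 for the EBF response of 35S:EBFS reared aphids and 0.9993 for the solvent comparison.

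Ratios were computed here with limma 3.58.1 in R 4.3.3. Median foreground and median background signals were corrected by normexp with an offset of 50; the mean foreground signal named in the design fixed beforehand was not used here. Loess within each array gave controls and flagged outlier spots a weight of 0, and outlier spots were left out (123 of 204480 values of tested probes). Each aphid probe had 1 spot. Saturated spots were kept. A probe was tested where it was well above background in at least 4 of the 8 channels of at least 1 of the 4 conditions. Ratios were turned by the dyes in the labels to EBF over solvent and 35S:EBFS over Col-0. The limma fit used all 16 arrays with 1 coefficient per comparison and a dye intercept, so that all comparisons shared 1 estimate of spread per probe. Averages were means of both coefficients of a factor, and the interaction was the mean of the difference between EBF responses and the difference between rearing ratios. P-values were moderated by eBayes, are two-sided, and were adjusted by Benjamini-Hochberg over the probes tested in each comparison, with a threshold of 0.05. The unadjusted counts at random are 0.05 of the probes tested.

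Up to 2 probes stood for a contig and were tested separately. A named contig is represented by its probe with the highest mean intensity. The rule fixed before the data were examined takes, in each comparison, the 2 largest rises and 2 largest falls among probes that passed with the same sign on all 4 arrays. The rule's further parts take genes with an annotation or from gene lists; the files hold contig numbers and sequence identifiers with no annotation, so those parts and the planned gene list tests could not be run. Simulated unchanged groups for shared conditions used the residual spread of each probe, the mean residual correlation of same-numbered arrays of the pair of comparisons (0.434 for the Col-0 response and exposed rearing, 0.0907 for the Col-0 response and solvent rearing), and 20 simulated data sets. No array repeated another: among 120 pairs of arrays the highest absolute correlation was 0.772.

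The limma fit was tested on simulated data with 1 residual spread per probe, shared by all comparisons, and independent noise on each array. The real arrays differed in spread between comparisons, and same-numbered arrays of the Col-0 response and exposed rearing correlated. The shares recovered and the false calls below therefore need not hold for the real arrays. For the exposed rearing comparison (12780 probes), changes of 0.5, 1, 1.5 and 2 on the log2 scale, in 50 probes each, were recovered in 56%, 76%, 94% and 94% of probes, with 15 false calls among 175. For the Col-0 response the shares were 54%, 78%, 94% and 92%, with 8 false calls among 167. Some aphid probes are printed repeatedly as controls: over these 12 probes with 10 spots each, the median SD of the log2 ratio within an array was 0.086, and between arrays of a comparison 0.294.

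Slide 1 held the Col-0 response and the exposed rearing comparison, and slide 2 held the other pair, scanned separately. Alternatives were Agilent's processed signals, no background subtraction, quantile normalisation of average intensities, the authors' matrix, no dye term, each comparison on its own arrays, a loop model with 3 condition coefficients, the replicate number as a block, a dye term per slide, the slide as a random block, all probes, only probes well above background in all 32 channels, trended and robust eBayes priors, and each array left out in turn. The interaction was also taken from EBF responses alone and from rearing ratios alone. Further alternatives chosen after seeing the data are named as such where they appear.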

Results

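Transcript levels were compared in the green peach aphid, *Myzus persicae*, between aphids that had or had not met their alarm pheromone, (E)-β-farnesene (EBF), and between colonies kept on different plants. Col-0 is a wild-type line of *Arabidopsis thaliana*, and the labels describe aphids from it as not habituated. The 35S:EBFS plants carry a pheromone synthase transgene, and the labels describe aphids from them as habituated to EBF. Groups of 50 aphids met 1 µg of EBF in hexane, or hexane alone, for 30 min. Total RNA of 4 conditions (rearing on Col-0 or 35S:EBFS, with EBF or solvent) was hybridised in pairs to 16 Agilent arrays with Alexa Fluor dyes, 4 arrays for each of 4 direct comparisons, with the dyes reversed on alternate arrays. The comparisons form a closed loop. The series design text calls the 4 replicates of each kind biological.

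The arrays held 14628 aphid probes for 10489 contigs and other sequences, of which 12780 probes for 8946 contigs and sequences were tested. The median spot signal of an array's channel lay between 1463.5 and 3278.25 on slide 1, which held both comparisons of EBF-exposed Col-0 aphids, and between 814 and 1734.25 on slide 2, which held the other pair. Between 68.4% and 81.4% of aphid probes were well above background on slide 1 and between 76.5% and 89.0% on slide 2. No probe was saturated on slide 1, and at most 4.22% of an array were saturated in the red channel on slide 2. The number of arrays limits the precision of the ratios. The files do not pair contigs with gene names: none of the identifiers matched the gene table (0 matches), so contigs are given by number and no gene group was tested.

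The first comparison asked how Col-0 reared aphids responded to the pheromone. No probe passed the test for EBF over solvent in Col-0 reared aphids (limma, Benjamini-Hochberg adjusted p under 0.05; 0 of 12780 probes, smallest adjusted p 0.0609), while 2070 probes had an unadjusted p under 0.05, against 639 at random. Of these, 935 had higher and 1135 lower values with EBF. Contig5598, chosen after its values were seen, had a log2 ratio of 2.09 ± 0.78 (SD, n = 4), or 4.26-fold, with positive values on all 4 arrays (1.02 to 2.90) and a limma adjusted p of 0.0609. The mean ratios of different pairs of arrays correlated across probes at r = 0.467 and r = 0.475. In the loop model, which takes each ratio from all routes round the loop, 790 probes passed (451 higher, 339 lower), and with processed signals 22 passed (10 higher, 12 lower). The loop model rests on the recorded dyes of slide 2, whose direction is in doubt. With a weight for each comparison, an alternative chosen after seeing the data, 59 probes passed (23 higher, 36 lower). With a dye term for each slide 41 passed (7 higher, 34 lower), and on slide 1 alone 0 passed (1709 at an unadjusted p under 0.05). Without exposed rearing replicate 1 or 4, 50 or 40 probes passed, and without solvent rearing replicate 1, 1 passed.

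The same question was asked of aphids reared on 35S:EBFS. No probe passed here either for EBF over solvent (limma, 0 of 12780 probes, smallest adjusted p 0.0738), and 1147 had an unadjusted p under 0.05, of which 805 were higher and 342 lower with EBF by the dyes in the labels. The loop of comparisons left the dye direction of this comparison, and of both slide 2 comparisons together, in doubt; turned, 342 would be higher and 805 lower. Contig1855, chosen after its values were seen, had the log2 ratio -1.10 ± 0.47 (SD, n = 4), negative on all 4 arrays, with a limma adjusted p of 0.0738. Its other probe gave -1.12. Values from different pairs of arrays correlated across probes at r = 0.519 and r = 0.567. Limma with a weight for each comparison, or with a dye term for each slide, passed 2 probes, as did leaving out replicate 3, and slide 2 alone passed 0 (1692 at an unadjusted p under 0.05). On its own arrays 0 passed in limma, with 2979 at an unadjusted p under 0.05, against 1917 for the Col-0 response on its own. The authors' deposited p-values were under 0.05 for 1888 probes here and 1827 in the Col-0 response. Which response had more unadjusted calls thus depended on the fit.

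Exposed aphids of both colonies were compared directly. The signs here give 35S:EBFS over Col-0 reared and follow the dyes in the labels; they oppose the header of the authors' deposited table, whose log2 ratios for this comparison correlated with these at r = -0.999 once turned the same way. In EBF-exposed aphids 619 probes for 491 contigs and sequences differed between rearing hosts (limma, adjusted p under 0.05), 438 of them (70.8%) lower and 181 higher in 35S:EBFS reared aphids. In the loop model the larger share turned: of 658 probes, 370 were higher and 288 lower. That model combines this comparison with those of slide 2, whose dye direction is in doubt, and was not run with any comparison turned. In the fit by comparison, the differences of 186 of the 619 probes exceeded 2-fold. Contig5568 had the log2 ratio -2.02 ± 1.19 (SD, n = 4; limma adjusted p = 0.0246) and contig5598 had -2.00 ± 1.11 (SD, n = 4; limma adjusted p = 0.0124), both negative on all 4 arrays. Contig5793 had 1.91 ± 1.35 (SD, n = 4; limma adjusted p = 0.0496) and contig8633 had 0.85 ± 0.59 (SD, n = 4; limma adjusted p = 0.0410), both positive on all 4 arrays. Contig5793 was well above background in 3 of the 4 35S:EBFS channels and 1 of the 4 Col-0 channels. Over 31 alternatives contig5793 lost its call in 18, and over 32 contig8633 lost its call in 13. Of 196 called probes listed first of a contig's pair, 195 had a second probe of the same sign and 128 a second probe that also passed. The mean ratios of different pairs of arrays correlated across probes at r = 0.0717 and r = 0.238.

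These calls rested on the spread shared by all 16 arrays. The arrays of this comparison varied most: the median SD of a probe between its 4 arrays was 0.393, against 0.271, 0.207 and 0.252 in the Col-0 response, the 35S:EBFS response and the solvent comparison. With limma on its own 4 arrays, and with a weight for each comparison, 0 probes passed, with 995 and 1348 at an unadjusted p under 0.05. Every other comparison also passed 0 on its own 4 arrays, so that 0 does not set this one apart. Their unadjusted counts there were higher: 1917 in the Col-0 response, 2979 in the 35S:EBFS response and 1490 in the solvent comparison. On slide 1 alone 137 passed (8 higher, 129 lower), and leaving out replicate 2 or replicate 3 of this comparison left 0 (2434 and 1613 at an unadjusted p under 0.05). In the authors' deposited table, whose values were adjusted by Benjamini-Hochberg here, 0 probes passed for this comparison and 1199 of the tested probes had an unadjusted p under 0.05.

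**Figure D1:**
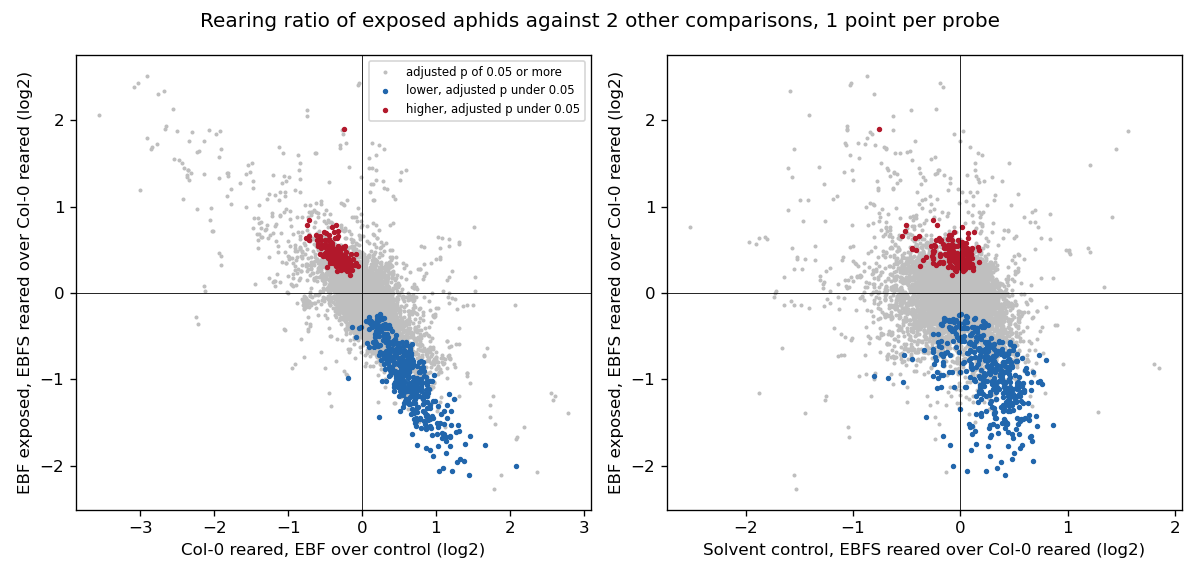
Log2 ratio of 35S:EBFS over Col-0 reared aphids exposed to EBF (vertical axis) against the EBF response of Col-0 reared aphids (left) and against the rearing ratio of solvent controls (right), 1 point per probe. Blue and red points are the 438 probes that were lower and the 181 that were higher in exposed 35S:EBFS reared aphids; in the right panel 369 of the 438 blue points lie right of 0 by the dyes in the labels, and 69 would if slide 2 were turned. The left panel's axes share the exposed Col-0 condition on opposite sides.

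The solvent controls were compared in the same way, asking how rearing host mattered without added pheromone. In limma 14 probes for 9 contigs fell in 35S:EBFS reared aphids (adjusted p under 0.05) and 0 rose, with 1238 at an unadjusted p under 0.05. These signs follow the dyes in the labels; were the dyes of slide 2 reversed, which stays open, all 14 would be higher. Values from different pairs of arrays correlated across probes at r = 0.232 and r = 0.392. Contig4831 fell with a log2 ratio of -1.30 ± 0.71 (SD, n = 4; limma adjusted p = 0.0223). Contig374 fell with -1.21 ± 0.19 (SD, n = 4; limma adjusted p = 0.00857), and its other probe gave -1.27. Both were negative on all 4 arrays. In exposed aphids the same probes had ratios of 0.15 and 0.03 (limma adjusted p 0.75 and 0.954), and none of the 14 passed there (0 shared calls). With limma on the comparison's own 4 arrays, or on slide 2 alone, 0 probes passed (1490 and 1526 at an unadjusted p under 0.05), 24 passed with a weight for each comparison, and 2, 4 and 2 passed without its replicates 2, 3 and 4.

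**Figure D2:**
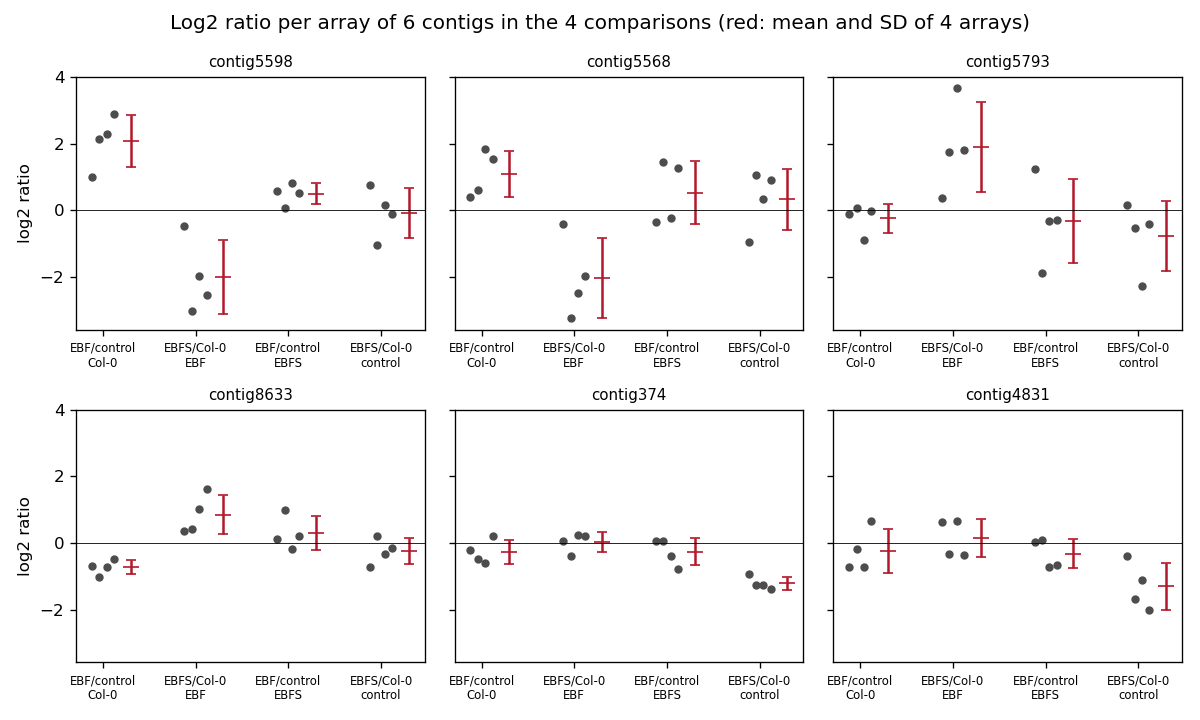
Log2 ratio of 6 contigs on each array (grey points) in the 4 comparisons, with the mean and SD of 4 arrays in red. The 4 values of contig374 in solvent controls lie between -1.38 and -0.94, and those of contig5598 in exposed aphids between -3.02 and -0.47.

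The design allows an average over both estimates of each factor. For rearing host averaged over exposure, 0 of 12780 probes passed in limma (smallest adjusted p 0.0565; 1516 at an unadjusted p under 0.05). With the dyes of both slide 2 comparisons turned, an alternative chosen after seeing the data because the loop left their direction in doubt, 537 passed (153 higher, 384 lower). For EBF averaged over rearing host, 0 probes passed in limma (smallest adjusted p 0.112; 1264 at an unadjusted p under 0.05, 915 of them higher). On the 8 arrays of the EBF comparisons alone, 194 probes passed for the EBF average, 190 of them higher. With the 35S:EBFS response turned, an alternative chosen after seeing the data, 0 passed on these arrays in limma (2527 at an unadjusted p under 0.05). With the 35S:EBFS response or both slide 2 comparisons turned, 12 passed in the fit of all arrays (4 higher, 8 lower). This is the difference between the EBF responses under the recorded dyes, with its sign changed. Likewise the 537 above are those of the difference between the rearing ratios. Both differences return below as estimates of the interaction and are not separate tests. Leaving out replicate 4 of the solvent comparison passed 32 for the EBF average, and leaving out replicate 4 of the Col-0 response passed 1 for rearing.

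Whether the pheromone response differed between rearing hosts was tested as an interaction over all 16 arrays. It is the mean of the direct difference between the EBF responses (35S:EBFS minus Col-0 reared) and the difference between the rearing ratios (exposed minus solvent), which estimate the same quantity if the loop closes. The direct difference of the EBF responses alone passed 12 probes (8 positive, 4 negative), and the difference of the rearing ratios alone passed 537 (153 positive, 384 negative). The larger share thus had opposite signs in these estimates. For the mean of both, 790 probes for 619 contigs and sequences passed in limma (adjusted p under 0.05), 454 with a positive and 336 with a negative value, and 356 of them also passed in the exposed rearing comparison. Among the positive 454, the median log2 EBF response was -0.36 in Col-0 reared and 0.17 in 35S:EBFS reared aphids. Among the negative 336, it was 0.51 in Col-0 reared and 0.12 in 35S:EBFS reared aphids. These probes were selected on a value that contains the difference between these responses, so the direction of that difference is built in. With the 35S:EBFS response turned, its medians of 0.17 and 0.12 for these same probes would change sign. Contig5598 had an interaction of -1.76 ± 0.32 (SE, 16 arrays, limma adjusted p = 0.0148). Its EBF response was 2.09 in Col-0 reared and 0.50 in 35S:EBFS reared aphids, and its rearing ratio was -2.00 in exposed and -0.06 in solvent aphids. Exposed Col-0 aphids enter both the 2.09 and the -2.00. The fit counted these arrays as independent, though same-numbered arrays of both comparisons correlated at 0.344 to 0.545. The error and p-value of this contig may therefore be too small. The contig was also chosen for its large rise in the Col-0 response and its large fall in exposed rearing. Both enter the interaction, so its negative value was favoured by the choice. With the 35S:EBFS response turned 1108 probes passed (296 positive, 812 negative), and with both slide 2 comparisons turned 121 passed (21 positive, 100 negative). The split therefore depends on the recorded dyes as well as on the estimate used. Taken as 1 value per replicate number, an alternative chosen after seeing the data, the interaction passed 0 probes in limma, with 2541 at an unadjusted p under 0.05. Leaving out single arrays gave 278 (without replicate 3 of the exposed rearing comparison) to 1037 probes (without its replicate 2). In the same way 371 and 314 probes passed without Col-0 response replicates 2 and 3, 291, 375 and 468 without 35S:EBFS response replicates 1, 2 and 3, and 447 and 382 without solvent replicates 2 and 4.

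Profiles of ratios were compared across the 12780 probes, which are not independent replicates. The EBF responses of the rearing groups, which share no condition, correlated at r = -0.0741 (Spearman's rho = -0.243), with a sign that turned between arrays left out: r lay between -0.170 and 0.187 (without replicate 2 of the 35S:EBFS response), and was 0.134 in the loop model. Turning the 35S:EBFS response would turn the sign of this r and rho as well. The rearing ratios of exposed and of solvent aphids, which share no condition, correlated at r = -0.263 (rho = -0.157), between -0.315 and -0.163 with single arrays left out. In the loop model, where the same shared noise raises r, it was 0.0276. Of the 438 probes lower in exposed 35S:EBFS reared aphids, 369 had a ratio above 0 and 69 a ratio below 0 in solvent controls (median log2 0.29). Of the 181 higher ones, 69 were above and 112 below 0 there (median log2 -0.04), and over all probes 48.0% had the same sign in both comparisons. With slide 2 turned, the signs of the solvent ratios, and so of these medians and of r, would turn, as would that of the next correlation. The EBF response of Col-0 reared aphids and the solvent rearing ratio, which share the Col-0 solvent condition, correlated at r = 0.0575 (rho = 0.153), between -0.0679 (without replicate 3 of the Col-0 response) and 0.330 (without replicate 2 of the solvent comparison). Unchanged simulated groups, with the mean correlation of same-numbered arrays of these comparisons (0.0907), gave r = 0.0883, and the covariance was 0.00503 against 0.00409 in the simulation, a difference of 0.000942. From arrays of different replicate numbers r was between -0.233 and 0.347.

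The EBF response of Col-0 reared aphids and the rearing ratio of exposed aphids share the exposed Col-0 condition, on opposite sides, and correlated at r = -0.720 (rho = -0.674). Without replicate 4 of the exposed rearing comparison r was -0.493. Unchanged simulated groups with a shared condition gave r = -0.431 and a covariance of -0.0200, and the observed covariance was -0.0887, a difference of -0.0687. From arrays of different replicate numbers r was between -0.567 and -0.110.

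The loop of comparisons gives a pair of routes from solvent-treated Col-0 aphids to exposed 35S:EBFS aphids, whose summed log2 ratios should be equal. Across probes the routes correlated at r = -0.397 (rho = -0.340), between -0.483 and -0.170 with single arrays left out, the weakest without replicate 2 of the exposed rearing comparison and -0.219 without replicate 2 of the solvent comparison. The median absolute difference was 0.23, against 0.19 from the standard errors alone, and 0 probes departed from equality in limma (adjusted p under 0.05), with 1357 at an unadjusted p under 0.05.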

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

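The tests of single-probe noise, of dyes recorded the wrong way round in the exposed rearing comparison, on slide 2 and in the 35S:EBFS response, and the alternatives with a weight per comparison, with correlated same-numbered arrays on slide 1 and with turned comparisons, were chosen after the data had been seen. Among 30 groups of 4 arrays no single array stood apart by Dixon's rule, which flags about 5% of groups by chance.

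The interaction of EBF exposure with rearing host was flagged because the mean of its 2 estimates passed 790 probes in limma, of which 356 were also calls of exposed rearing, while the difference between the EBF responses alone passed 12 and that between the rearing ratios alone 537. Random sign splits exclude chance only if arrays are independent: 2 of 100 splits, the real one included, gave as many probes, and the highest of the others, 815, turned only 2 of the 16 arrays. One technical account is that same-numbered arrays of the Col-0 response and the exposed rearing comparison may share the exposed Col-0 extract and were counted as independent; with their correlation of 0.424 in the fit, 191 probes passed, and as 1 value per replicate number 0 passed (2541 at an unadjusted p under 0.05), so this account stays open and with it the reading of the splits. A shift shared by the ratios of a slide cancels in this sum, and 891 probes passed with a dye term per slide and 759 with the slide as a random block, while a difference in scale between slides was not tested. A difference between habituated and other aphids remains open and untested beyond this.

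The rearing difference of exposed aphids (619 probes) was the largest count of a direct comparison in the pooled fit by comparison. It was not the largest in the loop model (658 against 790 for the Col-0 response). Nor was it the largest with a weight per comparison (0 against 59 and, for solvent rearing, 24). The loop model also rests on the recorded dyes of the slide without this comparison, whose direction is in doubt. That model was not run with any comparison turned, so its ranking may not hold. Noise of single probes is argued against, since 65.3% of called probes listed first of a contig's pair had a second probe that passed, against 4.67% of all second probes. Dyes recorded the wrong way round in this comparison were tested by its same-numbered arrays and those of its neighbours. Signed for a shared extract under the labels' dyes, the lowest of its 4 correlations with the Col-0 response was 0.344. With the EBF response of habituated aphids they were -0.528 to 0.264, and -0.617 to -0.0311 with a dye term per slide. The dye direction of that response is itself in doubt. The header of the authors' deposited table also runs against the labels' dyes. The values with the Col-0 response argue against wrong dyes only if those arrays share extracts, which is not known, so this stays open. A spread understated by pooling all arrays is consistent with the count: with a weight per comparison, which gave this comparison 0.543 and the others 1.1 to 1.38, 0 probes passed (limma; 1348 at an unadjusted p under 0.05), while the median absolute log2 ratio of the 619 probes stayed at 0.71 and its median SE grew from 0.157 to 0.213, so the calls ended through the larger error. The 8 sign splits of its 4 arrays are too few for a share under 0.05; 1 of the 8, the real one, gave 619 and the highest other gave 0.

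The routes round the loop correlated at -0.397 where equal sums were due, and at -0.170 without replicate 2 of the exposed rearing comparison. Chance cannot be excluded: 29 of 100 sign splits of the slide 2 arrays gave a correlation as far from 0 (real value -0.396 from plain means, highest other 0.652 in size). Dyes recorded the wrong way round for both slide 2 comparisons would make same-numbered correlations across slides negative. Their median was 0.0992 (SE 0.113, from -0.528 to 0.459). With a dye term per slide they were -0.617 to -0.0311 between exposed rearing and the 35S:EBFS response (independent arrays give 0). Between the Col-0 response and solvent rearing they were then -0.494 to 0.379, with 3 of 4 below 0. Their direction thus depended on the dye term, and same-numbered arrays are not known to share extracts, so this stays open. Dyes recorded the wrong way round in the 35S:EBFS response alone would make its correlations with both neighbours negative, and their median was -0.0637 (SE 0.104). With a dye term per slide all were negative, -0.617 to -0.0311 with exposed rearing and -0.745 to -0.390 with solvent rearing (independent arrays give 0 and -0.2). Same-numbered arrays on slide 2 are not known to share extracts, so this too stays open. Turning that response lowered the median absolute difference between the routes from 0.23 to 0.15, and turning both slide 2 comparisons lowered it to 0.17.

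The other sign splits add the following. For the Col-0 response 8 of 8 splits, and for the 35S:EBFS response 8 of 8, gave at least the real count of 0 (highest other 0), and for the solvent comparison 1 of 8 gave 14 (highest other 0); 8 splits are too few for a share under 0.05. For the rearing average 100 of 100 splits gave at least 0 probes; the highest, 750, turned 3 of the 4 solvent arrays, and turning all 4 gives the difference between the exposed and solvent rearing ratios, which passed 537. For the EBF average 100 of 100 splits gave at least 0 (highest other 0). Where the real count is 0 every split must reach it, so these shares were fixed in advance and say nothing about chance.

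A signal appeared in negative controls that no comparison used: the *Arabidopsis* probe At1g03880.1a was well above background in 64.1% of its spot channels. Every other *Arabidopsis* control probe was at 4.375% or less, with 1.88% for At1g03880.1b, the other probe of that name. The share was 2.53% for the negative controls that are not from *Arabidopsis* (18.3% for Alien1, the highest of them, and 3.44% for the next).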

How the results depend on the processing

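The weight per comparison, the fits of each slide alone, the turned comparisons, the fit without saturated spots, the single value per replicate number and the block on slide 1 were chosen after seeing the data; causes were not tested except where fewer arrays or probes show them. The authors' matrix, no background subtraction, the slide as a random block and the fit without saturated spots kept each count they were run for within 1.5 times, as did quantile normalisation, which leaves ratios as they are. The replicate block (consensus correlation 0.0204) gave 638 probes for exposed rearing, 14 for solvent rearing and 619 for the interaction, and changed no other call; same-numbered arrays did not pair throughout (8 of 16 correlations over 0.1, from -0.528 to 0.545), though all 4 between the Col-0 response and exposed rearing were. The Col-0 response passed 22 probes with processed signals, 41 with a dye term per slide, 790 in the loop model and 59 with the weight. Exposed rearing passed 324 among probes above background in all channels (fewer tested), 137 on slide 1 alone, and 0 on its own arrays, with the weight and in the authors' deposited table. The 35S:EBFS response passed 2 without a dye term, with a dye term per slide and with the weight. Solvent rearing passed 5 without a dye term, 24 with the weight, and 0 on its own arrays, in the loop model, in the authors' deposited table and on slide 2 alone. The rearing average passed 1 without a dye term, with the strict filter and with trended robust priors, and 537 with exposed rearing turned or slide 2 turned. The EBF average passed 2 with processed signals, 194 on its own arrays (0 there with the 35S:EBFS response turned), 13 with the weight, and 12 with slide 2 or the 35S:EBFS response turned. The interaction passed 12 from EBF responses alone, 0 as 1 value per number, 191 with the block on slide 1, 0 with exposed rearing turned, 121 with slide 2 turned (21 positive, 100 negative) and 1108 with the 35S:EBFS response turned (296 positive, 812 negative). The correlation of the rearing ratios reversed to 0.0276 in the loop model, which forces the routes to be equal. Its ratios then share noise that raises this correlation even without any effect. Leaving out single arrays gave 0 to 50 probes for the Col-0 response (50 and 40 without exposed rearing replicates 1 and 4, 1 without solvent replicate 1), 0 to 851 for exposed rearing (0 without its replicate 2 or 3), 0 to 2 for the 35S:EBFS response (2 without its replicate 3), 2 to 21 for solvent rearing (2, 4 and 2 without its replicates 2, 3 and 4), 0 to 1 for the rearing average (1 without Col-0 response replicate 4), 0 to 32 for the EBF average (32 without solvent replicate 4) and 278 to 1037 for the interaction (278 without exposed rearing replicate 3; 371 and 314 probes passed without Col-0 response replicates 2 and 3, 291, 375 and 468 without 35S:EBFS response replicates 1, 2 and 3, and 447 and 382 without solvent replicates 2 and 4). Of 319 alternative values of 10 contig ratios, 249 stayed on their side of the threshold, 54 lost a call (18 of them contig5793 and 13 contig8633 in exposed rearing), 16 gained one, and 0 changed sign. The turned comparisons were not run for contigs, and many of these alternatives leave a contig's ratio as it is. The 0 therefore does not bear on the dye direction, and turning slide 2 would turn the signs of its contigs. Gene lists were not run, as the files name no genes. Probes near background limit the weakest ratios, such as contig5793.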

Other observations

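The *Arabidopsis* control probe At1g03880.1a was above background on slide 1 in 100% of spot channels of exposed Col-0 aphids, 75% of solvent Col-0 aphids and 100% of exposed 35S:EBFS aphids. On slide 2 the shares were 52.5% in solvent Col-0, 47.5% in exposed 35S:EBFS and 18.75% in solvent 35S:EBFS aphids by the dyes in the labels. Were the dyes of slide 2 reversed, which stays open, its channels would change conditions and these shares would differ. Its mean log2 ratio was 0.99 ± 1.58 (SD, n = 4) for EBF over solvent in Col-0 reared aphids and -0.91 ± 0.88 (SD, n = 4) for rearing in solvent controls. It was -0.06 ± 0.36 (SD, n = 4) for EBF over solvent in 35S:EBFS reared aphids and -0.07 ± 0.71 (SD, n = 4) for rearing in exposed aphids. With slide 2 turned, the ratios of -0.91 and -0.06 would change sign.

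Same-numbered correlations depended on the dye term. With a dye term per comparison they were 0.407 to 0.465 between the Col-0 response and exposed rearing, -0.544 to -0.425 between exposed rearing and the 35S:EBFS response, -0.338 to -0.0656 between the 35S:EBFS response and solvent rearing, and -0.368 to 0.244 between the Col-0 response and solvent rearing, each signed so that a shared extract is positive under the labels' dyes. In that fit the deviations of replicates 1 and 3 mirror each other, as do those of replicates 2 and 4. Their correlations therefore repeat, and each range does not rest on 4 separate values.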
